A study of Homo sapiens with 6 samples.

How the data were processed

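RNA from WM164, a BRAF-mutant human melanoma line derived from a lymph node metastasis, was measured on 6 whole-transcript expression arrays. The Parent group held 3 samples given DMSO and the IDTC group (induced drug tolerant cells) held 3 samples given 500 nM PLX4032 (vemurafenib, an inhibitor of mutant BRAF) for 16 days, per the labels. No length of the DMSO treatment was found in the labels, so time in culture may differ between the groups. The group and the sample number were read from the sample titles. The design text of the series states that cells were kept in triplicate and that the mRNA of each sample was isolated on its own. It does not state whether the cultures came from separate experiments, so the p-values measure the spread between these samples, part of which may be technical.

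The deposited table held 33297 probe sets with log2 expression values on every array, and the authors had already normalized them. The submitters' processing notes name Affymetrix Expression Console, RMA (background correction, quantile normalization and probe summarisation) and Partek 6.6, without saying which tool did which step. The range of the values, from 1.82 to 13.9 over the arrays, is that of a log2 scale. The medians of the Parent arrays were 6.25, 6.32 and 6.32 and those of the IDTC arrays 6.29, 6.29 and 6.36. The interquartile range was 3.51 to 3.60 in the Parent arrays and 3.31 to 3.49 in the IDTC arrays, so the arrays did not share one distribution, and the step that left this difference is not given in the sources used here. The table carries no counts and no detection call, so whether a gene lay above background is unknown, and the fold change of a dim gene is likely understated by the background signal. The number of arrays limits the precision of every value.

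Gene names came from the platform annotation, which listed 21214 of the probe sets. Of these, 19460 had 1 gene symbol and 1754 had several, and 12083 probe sets were not listed. Only probe sets with 1 symbol were named. Of these, 19429 matched a human gene record of the GRCh38.p14 annotation through their gene number and 31 did not. That annotation was used for names only, no symbol changed, and no coordinates are given because the files name no genome build. Where several probe sets shared a symbol (769 genes), the one with the highest mean over the 6 arrays stood for the gene, which left 18417 genes. Among the genes taken by the rule for named genes given below, the probe sets of a gene moved the same way except for UHRF1. Its chosen probe set had a log2 fold change of -2.52 and its dimmer one -0.20, which was not called. Probe sets of genes named outside that rule were not compared.

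Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, all 6 arrays, no covariates, no filter on dim genes). The direction is IDTC minus Parent throughout. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the words rose and fell are used only for called genes. Adjusted p-values in the text come from this fit unless another test is named. Values of single genes are means ± SD of log2 expression (n = 3 per group), and the error of a log2 fold change is its standard error.

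The design, the alternatives, the rule for named genes and 34 gene lists were fixed before the data were examined. Each list was tested against all other genes with camera (limma, preset inter-gene correlation 0.01, adjusted over the 34 lists). Beside each called list stands the adjusted p that camera gave with a correlation estimated from the list itself. That form of the test rests on the 4 residual degrees of freedom of the 6 arrays. Another 12 lists were written after the gene table had been seen and are reported apart.

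The genes named were, by the rule fixed in advance, the 12 with the highest and the 12 with the lowest log2 fold change among genes called at 2-fold or more whose groups did not overlap. From each list came up to 4 called members with the largest absolute change, or up to 2 members given as values where none was called. NGFR, ABCB5, KDM5A, KDM5B, KDM6B, BRAF, MITF, SOX10, AXL, EGFR, DUSP6, SPRY4, CCND1, MKI67, CDKN1B, TYRP1 and MLANA were always included, of which BRAF was not analysed here. Members of a list that are named outside this rule, mostly those that moved against the rest of their list, were chosen after their values were seen.

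The procedure was tested on simulated data in which 200 of the 18417 genes were changed by known amounts on the measured spread. It recovered 58% of 50 genes changed by 0.5 log2, 96% of 50 changed by 1, 98% of 50 changed by 2 and 100% of 50 changed by 3, and it called 9 unchanged genes. Of 200 random lists, 6 had a camera p under 0.05. The simulated genes were drawn independently of each other, so this gives no error rate for lists whose genes vary together. Far fewer genes were changed than the 8588 called in the data. The p cutoff of the Benjamini-Hochberg adjustment depends on that share, so the recovery and the false calls do not carry over to the data. The alternatives were re-centred arrays, another quantile normalization, a filter on the dimmest 40% of genes, every probe set tested on its own, the mean of a gene's probe sets, a variance model with an intensity trend and robust estimation, array weights, the sample number as a block, each array left out in turn, stricter thresholds, a test against a 1.5-fold minimum (treat), and for the lists an estimated correlation, fry (a rotation test of each list on its own) and lists without shared members.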

Results

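Expression was compared between WM164 melanoma cells given only the vehicle DMSO (Parent, 3 arrays) and WM164 cells that had been kept in the BRAF inhibitor PLX4032 at 500 nM for 16 days (IDTC, 3 arrays). The comparison asks which genes differ between the parental line and the drug-tolerant cells present at the end of the treatment. Over 18417 genes, arrays of one group correlated at r = 0.995 to 0.998 and arrays of different groups at r = 0.953 to 0.957. The first principal component carried 89.7% of the variance and separated the groups, and the second carried 5.33%.

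In the drug-tolerant cells 20 of 25 genes that report MAPK pathway activity fell, as did all 37 measured genes of DNA replication and all 24 of ribosome biogenesis. Genes of pigmentation, the neural crest and the lysosome rose in 17 of 22, 13 of 22 and 15 of 22 cases. Camera called each of these lists at its preset correlation and none of them with an estimated correlation (adjusted p = 0.143 to 0.295). SPRY4, a feedback inhibitor of receptor signalling induced by ERK, fell from 11.90 ± 0.04 to 6.66 ± 0.36 (37.7-fold). The growth factor binding protein gene IGFBP5 fell from 10.92 ± 0.02 to 5.56 ± 0.13 (41.0-fold). ANGPTL7, an angiopoietin-like secreted factor, rose from 5.13 ± 0.10 to 9.43 ± 0.05 (19.8-fold), and MMP2, the gelatinase that degrades basement membrane collagen, from 8.04 ± 0.04 to 11.79 ± 0.03 (13.5-fold). The adjusted p was 7.5e-08 for IGFBP5 and MMP2, 8.8e-08 for ANGPTL7 and 6.5e-07 for SPRY4, and for each of the 4 genes all arrays of one group lay on one side of the other group.

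In all, 8588 genes (46.6%) were called, of which 3996 rose and 4592 fell. This balance turned with the scaling, with 4846 higher and 4017 lower after re-centring the arrays and 4504 and 4403 after quantile normalization. A change of 2-fold or more was found for 1696 genes, 701 of them higher and 995 lower, and 250 genes changed by 4-fold or more. Of the called genes, 3920 changed by less than 0.5 log2. The groups did not overlap for 9967 genes (54.1%), where chance gives 10%. Besides SPRY4 and IGFBP5, the 12 lowest genes were the cytokine gene LIF (fell by 5.13 ± 0.07 log2), FCRLA (fell by 4.79 ± 0.07), CD96 (fell by 4.60 ± 0.08), the matrix link protein gene HAPLN1 (fell by 4.56 ± 0.06), the ETS factor gene ETV4 (fell by 4.24 ± 0.06), the matrix glycoprotein gene TNC (fell by 4.09 ± 0.06), CYB5R2 (fell by 3.97 ± 0.10), SPRR2D (fell by 3.85 ± 0.12), KIAA0040 (fell by 3.82 ± 0.07) and the calcium-binding protein gene S100A16 (fell by 3.65 ± 0.06). Besides ANGPTL7 and MMP2, the 12 highest were STK32A (rose by 4.04 ± 0.09), SLITRK6 (4.03 ± 0.10), ADHFE1 (4.03 ± 0.09), TFAP2A-AS1 (3.89 ± 0.07), RFTN2 (3.89 ± 0.07), the inhibitor of basic helix-loop-helix factors ID2 (3.89 ± 0.10), the proteoglycan gene BCAN (3.75 ± 0.06), PRUNE2 (3.68 ± 0.10), FSTL1 (3.60 ± 0.08) and the axon guidance gene SEMA3D (3.58 ± 0.07). TFAP2A-AS1 and its neighbour on the other strand, TFAP2A, both rose.

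**Figure D1:**
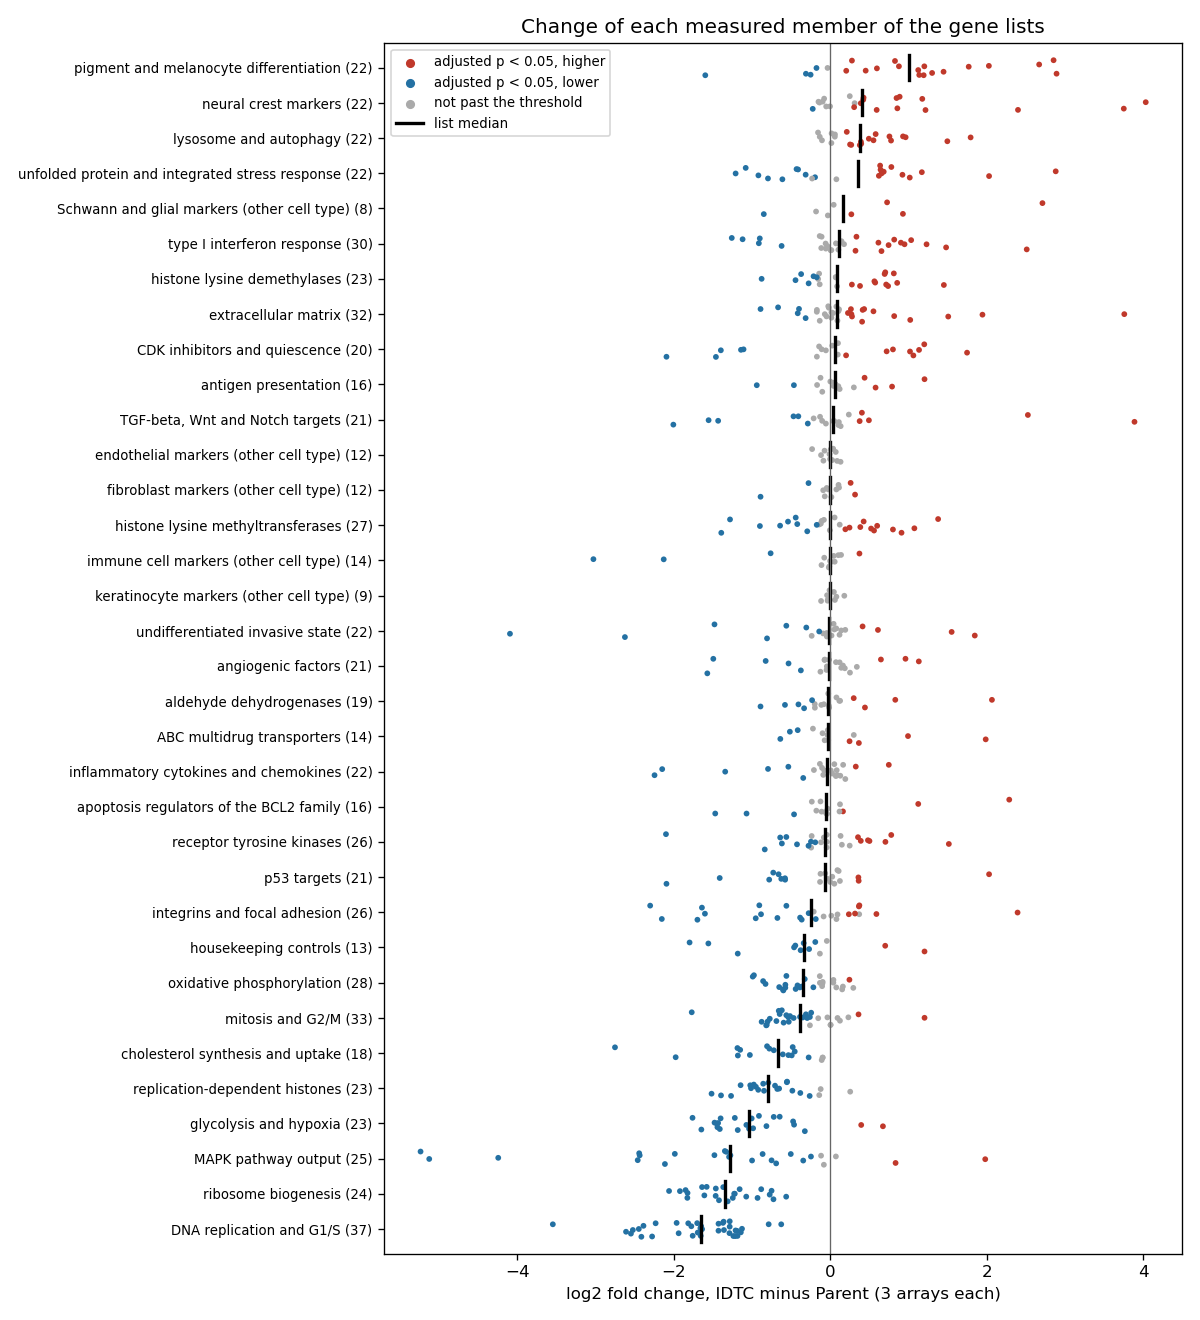
Log2 fold change (IDTC minus Parent, horizontal axis) of each measured member of the 34 gene lists, 1 line per list with the number of measured members in brackets, sorted by the list median. Points are genes, red where called higher, blue where called lower and grey where not called, and black bars are list medians, which run from -1.65 for DNA replication and G1/S to 1.00 for pigment and melanocyte differentiation.

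Of the 25 measured MAPK output genes, 20 fell, 2 rose and 3 were not called (median log2 fold change -1.28, adjusted p = 9.41e-08, and adjusted p = 0.143 with an estimated correlation). Besides SPRY4, LIF and ETV4, ETV1 fell by 2.46 ± 0.07 and DUSP6, the phosphatase that inactivates ERK, by 2.44 ± 0.06. CCND1, which encodes cyclin D1, fell by 1.00 ± 0.06, from 10.71 ± 0.02 to 9.70 ± 0.06. The 2 members that rose were the immediate early genes FOS (1.98) and EGR1 (0.83).

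Every one of the 37 measured DNA replication and G1/S genes fell, 35 of them by 2-fold or more (median -1.65, adjusted p = 6.33e-20, and adjusted p = 0.174 with an estimated correlation). CDC6, which loads the replicative helicase, fell by 3.55 ± 0.07, the checkpoint mediator gene CLSPN fell by 2.61 ± 0.11 and the cyclin gene CCNE2 fell by 2.55 ± 0.11. Replication-dependent histone genes fell in 20 of 23 cases, with 3 not called (median -0.79, adjusted p = 2.61e-07, and adjusted p = 0.318 with an estimated correlation), among them H2AC4 (-1.52 ± 0.09) and H2BC3 (-1.40 ± 0.14), whose near-identical copies make the values of single histone genes uncertain. Genes of mitosis and G2/M moved less. Of 33 measured, 23 fell, 2 rose and 8 were not called (median -0.39, adjusted p = 9.76e-04, and adjusted p = 0.712 with an estimated correlation). The spindle checkpoint gene MAD2L1 fell by 1.77 ± 0.15, whereas the mitotic kinesin gene KIF20A rose by 1.20 ± 0.06 and CENPF by 0.36. The proliferation marker MKI67 fell by 0.24 ± 0.07 (adjusted p = 0.018), a call that was lost when the arrays were re-centred on their medians (adjusted p = 0.055). The mean of the G1/S genes minus that of the G2/M genes was 0.452 ± 0.0475 (SD, n = 3) in Parent and -0.873 ± 0.0535 in IDTC arrays, a difference of -1.32 (exact permutation test, 2-sided, p = 0.1, the smallest this design allows). Tested with camera among the genes of both lists alone, the G1/S genes had the lower fold changes (p = 1.39e-09, and p = 0.0308 with an estimated correlation). These comparisons of the G1/S with the G2/M genes were not in the design fixed in advance. Their p-values are therefore not independent evidence.

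CDK inhibitors and quiescence genes went both ways. Of 20 measured, 8 rose, 5 fell and 7 were not called (median 0.06, adjusted p = 0.532). CDKN1B, which encodes p27, rose by 1.02 ± 0.06 and SESN3 by 1.75 ± 0.06, whereas CDKN1A, which encodes p21, fell by 2.09 ± 0.08 and CDKN2B by 1.46 ± 0.07. CCND3, a cyclin gene in this list and not a CDK inhibitor, fell by 1.40 ± 0.06. Among 21 p53 targets, 8 fell, 3 rose and 10 were not called (median -0.07, adjusted p = 0.261), with TNFRSF10B (-1.41 ± 0.06) and GDF15 (-0.78 ± 0.05) lower and SESN2 (2.03 ± 0.09) higher. Among 16 BCL2 family genes, 3 rose, 3 fell and 10 were not called (median -0.06, adjusted p = 0.919). The pro-apoptotic BMF rose by 2.29 ± 0.08 and the anti-apoptotic BCL2A1 by 1.12 ± 0.08, while the pro-apoptotic PMAIP1 fell by 1.47 ± 0.09 and BID by 1.07 ± 0.06.

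Genes of pigment and melanocyte differentiation rose in 17 of 22 cases, with 4 lower and 1 not called (median 1.00, adjusted p = 2.98e-06, and adjusted p = 0.295 with an estimated correlation). TYRP1, a melanosomal enzyme, rose from 4.69 ± 0.10 to 7.58 ± 0.25 (7.41-fold), MLPH by 2.85 ± 0.09, EDNRB by 2.67 ± 0.07 and the melanoma antigen gene MLANA by 1.45 ± 0.05. The 4 that fell were MC1R (-1.60), ST3GAL6 (-0.31), IRF4 (-0.25) and SLC24A5 (-0.18). MITF, the transcription factor that drives many of these genes, was not called, at 11.14 ± 0.01 in Parent and 11.10 ± 0.09 in IDTC cells. Neural crest markers rose in 13 of 22 cases, with 1 lower (GFRA2, -0.23) and 8 not called (median 0.40, adjusted p = 1.59e-04, and adjusted p = 0.143 with an estimated correlation). Without the dimmest 40% of genes the median of this list was 0.85. Besides SLITRK6 and BCAN, TFAP2A rose by 2.40 ± 0.05, PAX3 by 1.22 ± 0.07, SOX10 by 0.85 ± 0.05 and NGFR, the nerve growth factor receptor gene, by 0.89 ± 0.08, from 7.31 ± 0.13 to 8.20 ± 0.09. The markers of an undifferentiated invasive state were split, with 4 higher, 7 lower and 11 of 22 not called (median -0.01, adjusted p = 0.919). TNC, NT5E (-2.62 ± 0.09) and EGFR (-0.56 ± 0.09) fell, CCN2 (1.85 ± 0.06) and SNAI2 (1.55 ± 0.06) rose, and AXL was not called, at 6.02 ± 0.11 and 5.97 ± 0.16.

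**Figure D2:**
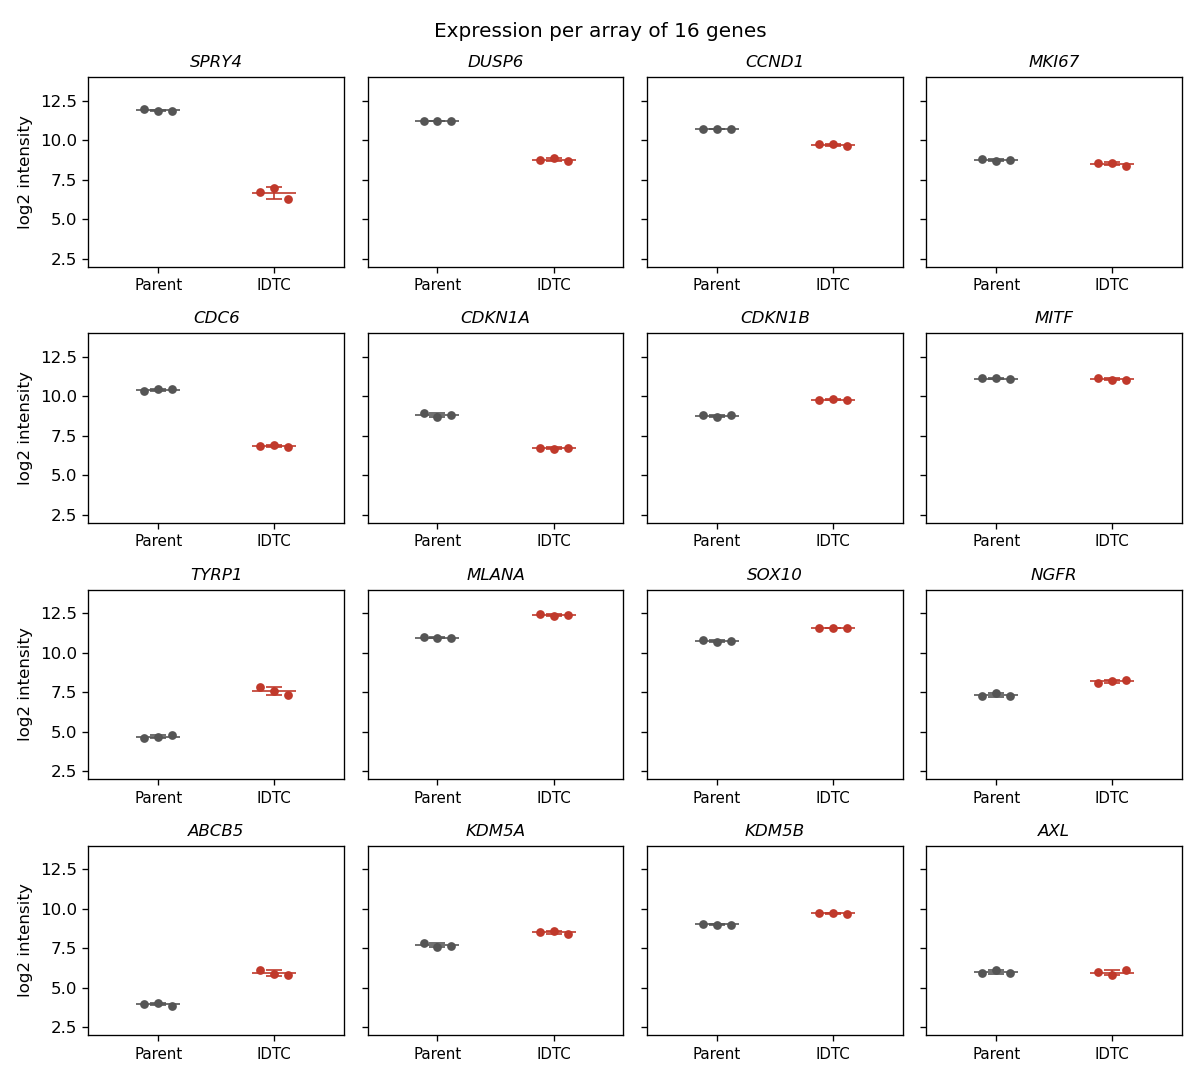
Log2 intensity (vertical axis, from 2 to 14) of 16 genes on each of the 6 arrays. Points are arrays, grey for Parent and red for IDTC, and horizontal bars with whiskers are means ± SD of 3 arrays. SPRY4 and CDC6 lie far lower in IDTC, TYRP1 and ABCB5 lie higher, and the groups overlap for MITF and AXL.

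Histone lysine demethylase genes rose in 11 of 23 cases and fell in 6, with 6 not called (median 0.09, adjusted p = 0.166). The median depended on the scaling and on single arrays, at 0.15 after re-centring, 0.18 after quantile normalization, 0.04 without IDTC 1 and 0.19 without IDTC 3. KDM4A rose by 1.45 ± 0.06, KDM3B by 0.85 ± 0.09, KDM5A by 0.81 ± 0.08, KDM5B by 0.71 ± 0.06 and KDM6B by 0.28 ± 0.06. JMJD6, a gene in this list and not an established histone lysine demethylase, fell by 0.88 ± 0.05. Of 27 histone lysine methyltransferase genes, 11 rose, 9 fell and 7 were not called (median -0.01, mean 0.03, adjusted p = 0.848, with the test pointing up), with SETDB2 (1.38 ± 0.12) and EZH1 (1.07 ± 0.07) higher and the H3K79 methyltransferase gene DOT1L (-1.39 ± 0.05) lower. Among 14 ABC multidrug transporter genes, 4 rose, 3 fell and 7 were not called (adjusted p = 0.919), and the list median (-0.04) differed in sign from the mean (0.13) and the test. ABCB5 rose from 3.96 ± 0.07 to 5.95 ± 0.19 (3.96-fold, adjusted p = 4.1e-06), a low level on these arrays, and ABCA5 rose by 0.99 ± 0.08, while ABCG2 fell by 0.64 ± 0.09. Among 19 aldehyde dehydrogenase genes, 4 rose, 5 fell and 10 were not called (median -0.03, mean 0.04, adjusted p = 0.929, with the test pointing down), with ALDH6A1 (2.06 ± 0.07) highest and ALDH18A1 (-0.89 ± 0.07) lowest.

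Of 23 glycolysis and hypoxia genes, 21 fell and 2 rose (median -1.04, adjusted p = 5.30e-09, and adjusted p = 0.143 with an estimated correlation). The hexokinase gene HK1 fell by 1.76 ± 0.10, the glucose transporter gene SLC2A1 by 1.65 ± 0.05 and PDK1 by 1.48 ± 0.07, and the 2 that rose were EGLN3 (0.67) and PFKM (0.39). Cholesterol synthesis and uptake genes fell in 15 of 18 cases, with 3 not called (median -0.67, adjusted p = 2.25e-06, and adjusted p = 0.295 with an estimated correlation), led by DHCR7 (-2.75 ± 0.06) and STARD4 (-1.98 ± 0.12). All 24 ribosome biogenesis genes fell (median -1.34, adjusted p = 4.28e-13, and adjusted p = 0.195 with an estimated correlation), among them MRTO4 (-2.06 ± 0.10) and NOP2 (-1.92 ± 0.05). Oxidative phosphorylation genes fell in 16 of 28 cases, with 1 higher (NDUFA2, 0.24) and 11 not called (median -0.35, adjusted p = 3.62e-03, and adjusted p = 0.526 with an estimated correlation). CYCS fell by 0.99 ± 0.12 and NDUFV2 by 0.98 ± 0.07, and the call of this list was lost after quantile normalization between the arrays (adjusted p = 0.0724). Lysosome and autophagy genes rose in 15 of 22 cases and fell in none, with 7 not called (median 0.38, adjusted p = 7.73e-05, and adjusted p = 0.147 with an estimated correlation). The lysosomal hydrolase genes HEXA, TPP1 and CTSD rose by 1.79 ± 0.05, 1.49 ± 0.05 and 0.96 ± 0.06. Of 22 genes of the unfolded protein and integrated stress response, 11 rose, 9 fell and 2 were not called (median 0.35, adjusted p = 0.304), and the median was 0.08 for the members held by no other list. The stress-induced transcription factor gene DDIT3 rose by 2.88 ± 0.06, SESN2 by 2.03 ± 0.09 and the serine synthesis gene PSAT1 by 1.17 ± 0.07, whereas the chaperone gene PDIA4 of the endoplasmic reticulum fell by 1.21 ± 0.05.

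Lists of the cell surface and its signals were not called. Extracellular matrix genes rose in 13 of 32 cases, fell in 5 and were not called in 14 (median 0.08, adjusted p = 0.0758), and the median was 0.02 without Parent 1. This list passed the threshold without the dimmest 40% of genes (median 0.27, adjusted p = 0.0230) and with the members held by no other list (median 0.16, adjusted p = 0.0417). Besides MMP2, its inhibitor gene TIMP2 rose by 1.94 ± 0.05 and the laminin genes LAMB2 and LAMB1 by 1.51 ± 0.06 and 1.02 ± 0.05. Integrin and focal adhesion genes fell in 14 of 26 cases, rose in 6 and were not called in 6 (median -0.24, adjusted p = 0.0861), with ITGA4 (-2.30 ± 0.07), ACTN1 (-2.15 ± 0.06) and ITGB3 (-1.70 ± 0.05) lower and the collagen-binding ITGA2 (2.39 ± 0.07) higher. Of 26 receptor tyrosine kinase genes, 7 rose, 9 fell and 10 were not called (median -0.07, adjusted p = 0.919), with MERTK (-2.10 ± 0.05) and DDR2 (1.51 ± 0.06) farthest apart. Of 21 TGF-beta, Wnt and Notch targets, 5 rose, 6 fell and 10 were not called (median 0.04, adjusted p = 0.919). ID2 and ID3 (2.52 ± 0.05) rose, and HEY1 (-2.01 ± 0.05) and TGFB1 (-1.56 ± 0.11) fell. Of 21 angiogenic factor genes, 3 rose, 5 fell and 13 were not called (median -0.02, mean -0.06, adjusted p = 0.848, with the test pointing up), with KITLG (-1.57 ± 0.20) and PGF (-1.50 ± 0.10) lower and FGF1 (1.13 ± 0.08) higher.

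Immune signalling lists were not called either. Of 30 type I interferon response genes, 12 rose, 5 fell and 13 were not called (median 0.10, close to 0 without the dimmest 40% of genes, adjusted p = 0.146). SAMD9L rose by 2.51 ± 0.09, IFIT1 by 1.48 ± 0.09 and IFIT2 by 1.23 ± 0.22, and PARP9 fell by 1.26 ± 0.11. Of 16 antigen presentation genes, 4 rose, 2 fell and 10 were not called (median 0.06, adjusted p = 0.532). B2M, the light chain of class I molecules, rose by 1.20 ± 0.12, and the peptide transporter gene TAP2 fell by 0.94 ± 0.07. Of 22 inflammatory cytokine and chemokine genes, 2 rose, 6 fell and 14 were not called (median -0.04, adjusted p = 0.658), with CCL20 (-2.25 ± 0.07), TNFAIP3 (-2.15 ± 0.09) and PTGS2 (-1.34 ± 0.18) lower.

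Markers of other cell types gave no list that was called. Among 9 keratinocyte and 12 endothelial markers, limma called none, and none had an unadjusted p under 0.05. The adjusted p of these lists was 0.919 and 0.929, and their median and mean were of opposite sign or 0 (-0.01 and 0.01 for keratinocyte, 0.00 and -0.02 for endothelial markers). DSC3 had the largest difference of the former (0.18 ± 0.08) and PLVAP of the latter (-0.23 ± 0.10). Of 12 fibroblast markers, 2 rose, 2 fell and 8 were not called (median -0.01, mean -0.04, adjusted p = 0.919, with the test pointing up). LUM fell by 0.89 ± 0.14 and PDGFRA by 0.28 ± 0.06, and the rises of ACTA2 (0.32 ± 0.11) and FAP (0.26 ± 0.08) were lost under several alternatives. Of 14 immune cell markers, 3 fell, 1 rose and 10 were not called (median -0.01, adjusted p = 0.613). The 3 were LYZ (-3.03 ± 0.09), FCER1G (-2.13 ± 0.12) and CD68 (-0.76 ± 0.05), and the rise of MS4A1 (0.37 ± 0.12) was lost under several alternatives. Of 8 Schwann and glial markers, 4 rose, 1 fell and 3 were not called (median 0.16, and 0.50 without the dimmest 40% of genes, adjusted p = 0.193), with MBP, a myelin protein gene, higher by 2.71 ± 0.06 and S100B (-0.85 ± 0.07) lower. Housekeeping genes fell in 9 of 13 cases, rose in 2 and were not called in 2 (median -0.34, adjusted p = 0.0336, and adjusted p = 0.712 with an estimated correlation). HPRT1 fell by 1.80 ± 0.14, TFRC by 1.56 ± 0.06 and PGK1 by 1.18 ± 0.06, and B2M and GUSB (0.70) rose. The call of this list was lost after quantile normalization (adjusted p = 0.0956), without Parent 1 (0.0824) and without IDTC 3 (0.0567).

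Of the 34 lists, camera called 12, of which 3 lay higher and 9 lower. With an estimated correlation none was called, and 6 had an unadjusted p under 0.05. Adjusted over the list alone, the counts of members higher and lower were the same as those over all genes for 23 lists. They differed for 11, with 11 higher and 7 lower demethylases, 2 and 24 mitosis genes, 1 and 6 cytokines, 7 and 14 integrin genes, 8 and 9 receptor tyrosine kinases and 2 and 17 oxidative phosphorylation genes. For the stress response they were 11 and 10, for the lysosome 15 and 1, for the histones 1 and 22, for fibroblast markers 1 and 2 and for immune markers 0 and 3.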

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

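The counts of this part were made on probe sets outside the gene table, and the tests on them were added after the deposited values had been examined. Of the 12083 probe sets that the annotation used here did not list, 1809 were called and 339 differed by 2-fold or more between IDTC and Parent arrays, 179 of them higher and 160 lower. That is 2.81% of these probe sets, against 9.21% of the 18417 genes, at a median level of 5.08 against 6.96 for the genes. Each kind of probe set was fitted and adjusted on its own. Calls and shares here thus rest on another p cutoff than those of the genes and are not directly comparable. Of the 1754 probe sets with several gene symbols, 898 were called and 163 differed by 2-fold or more, 116 higher and 47 lower (9.29%). Both drew attention because they are signals outside the gene comparison, with the Parent arrays as the control. No gene was named from either kind of probe set, and no explanation was tested for them.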

How the results depend on the processing

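All alternatives of this part were fixed in advance, and no test was added after a result was seen. Genes called numbered 7375 to 10480 and genes called at 2-fold or more 1529 to 1786 over the other normalizations, filters, probe set rules, variance models and arrays left out. At an adjusted p under 0.01, 6741 genes were called, and treat against a 1.5-fold minimum called 2320. A minimum of 1.5 log2 left 607 genes (263 higher, 344 lower) by construction. Higher and lower calls numbered 4846 and 4017 after re-centring and 4504 and 4403 after quantile normalization, so the excess of lower calls was lost under both. Re-centring the arrays gave 800 higher and 881 lower genes at 2-fold, quantile normalization 819 and 859. Of 157 named genes, 150 kept their side of the threshold under all 14 alternatives run on them, and ACTA2, DSC3, FAP, MKI67, MS4A1, PLVAP and UHRF1 changed side under at least 1. No called list or named gene turned its direction, but the medians of 15 lists that were not called changed sign under at least 1 alternative, as did the values of MITF, AXL and SFN, which were not called. The undifferentiated state median was 0.05 and the methyltransferase median 0.06 after re-centring.

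Camera with an estimated correlation ended all 12 list calls, in part by construction, since it tests on 4 degrees of freedom: adjusted p = 0.143 for MAPK output, neural crest and glycolysis, 0.147 for lysosome, 0.174 for G1/S, 0.195 for ribosome biogenesis, 0.295 for pigment and cholesterol, 0.318 for histones, 0.526 for oxidative phosphorylation, and 0.712 for G2/M and housekeeping genes. Fry, which does not compare a list with other genes, called 28 lists, 16 of them new: extracellular matrix (adjusted p = 0.000125), integrins (0.000155), Schwann markers (0.000300), stress response (0.000461), undifferentiated state (0.000500), p53 targets (0.000566), interferon (0.00197), antigen presentation (0.00228), CDK inhibitors and immune markers (0.00367 each), cytokines (0.00491), demethylases (0.0117), receptor tyrosine kinases (0.0155), TGF-beta, Wnt and Notch targets (0.0328), ABC transporters (0.0329) and angiogenic factors (0.0492). Extracellular matrix genes were also called without the dimmest 40% of genes (0.0230) and with members in no other list (0.0417). Quantile normalization ended the calls of oxidative phosphorylation (0.0724) and housekeeping genes (0.0956). The latter call also ended without the dimmest genes (0.128) and with array weights (0.0781), and ranged from 0.0220 to 0.0824 with an array left out (0.0824 without Parent 1, 0.0567 without IDTC 3). Where no construction is named, the cause was not tested.

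With the sample number as a replicate block, 8855 genes were called (4148 higher, 4707 lower) and 1696 at 2-fold or more. The deviations of equally numbered arrays correlated at 0.31, -0.19 and 0.26, and those of differently numbered arrays at -0.47 to 0.37. Not every array correlated best with its own number. With 3 arrays per group these values cannot tell whether the numbers pair the samples. The level limits what can be seen: with genes ranked by level into 5 equal groups, 0.841% of the dimmest and 15.5% of the brightest were called at 2-fold or more.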

Other observations

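The gene lists of this part and the test of the heat shock genes alone were chosen only after the gene table had been seen, so their p-values are not independent evidence. All 24 measured proteasome subunit genes fell (median log2 fold change -0.90, camera adjusted p = 8.61e-12 over 12 lists, and adjusted p = 0.180 with an estimated correlation), led by PSMD14 (-1.58) and PSMB3 (-1.45). Mitochondrial ribosome genes fell in 20 of 24 cases and rose in 1 (median -0.75, adjusted p = 3.38e-07, and adjusted p = 0.180 with an estimated correlation). Nucleotide synthesis genes fell in 18 of 20 cases and rose in 1 (median -0.90, adjusted p = 3.38e-07, and adjusted p = 0.180 with an estimated correlation), with CTPS1 (-1.92) and PPAT (-1.65) lowest. Homologous recombination and Fanconi genes fell in 14 of 16 cases and rose in 1 (median -1.02, adjusted p = 3.09e-06, and adjusted p = 0.188 with an estimated correlation), with EXO1 at -1.93. Aminoacyl-tRNA synthetase genes were split, with AARS1 (1.24) highest and VARS1 (-1.62) lowest among 6 that rose, 8 that fell and 5 not called (median -0.10, adjusted p = 0.671).

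Every one of the 15 measured protocadherin beta genes, neighbours in 1 cluster that encode neuronal adhesion proteins, rose (median 1.38, adjusted p = 9.65e-09, and adjusted p = 0.180 with an estimated correlation). PCDHB5 rose by 3.09 ± 0.08 and PCDHB7, the lowest, by 0.56 ± 0.11. The genes are near-identical in places, so whether their probe sets share signal is unknown and the number of separate rises is uncertain. Of 19 semaphorin and plexin genes, 11 rose and 6 fell (median 0.29, adjusted p = 0.0220, and adjusted p = 0.285 with an estimated correlation), with SEMA3C (2.18) after SEMA3D and SEMA3A (-1.45) lower. Kruppel-like factor genes rose in 8 of 14 cases and fell in 2 (median 0.44, adjusted p = 0.0186, and adjusted p = 0.180 with an estimated correlation). S100 genes fell in 7 of 18 cases and rose in 0, with 11 not called (median -0.12, adjusted p = 0.00923, and adjusted p = 0.180 with an estimated correlation), with S100A3 (-2.94) after S100A16. Of 20 tetraspanin genes, 7 rose and 5 fell (median 0.01, adjusted p = 0.567).

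The number of genes called between the groups was set against other groupings of the arrays. The 6 arrays can be split into 3 and 3 in 10 ways. The real split called 8588 genes with limma and the other 9 called at most 0, with 39 to 1393 genes at an unadjusted p under 0.05 against 9653. Only 1 split, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Each of the others mixed Parent and IDTC arrays in both of its groups, so the difference between Parent and IDTC widened the spread within them. Few calls there were thus built in and say nothing about chance.

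Of the measured genes, 21 of 23 in glycolysis, 24 of 24 in ribosome biogenesis, 37 of 37 in DNA replication and 15 of 18 in cholesterol synthesis fell, in lists whose calls were lost with an estimated correlation (adjusted p = 0.143 to 0.295). The IDTC arrays had a narrower range of values, which could pull bright genes down. After quantile normalization, which gives the arrays one range, the median of the 102 genes was -1.17, which argues against that range as the whole cause. It lay below the 2.5th percentile (-0.117) of 10000 lists matched on mean expression. The lists were chosen because they had fallen, so this position is not independent evidence. Less oxygen in the Parent cultures, with higher HIF activity there, stays open for the glycolysis genes. Of 18 HIF targets outside the glycolysis list, 11 fell, 3 rose and 4 were not called (camera adjusted p = 0.00923, and adjusted p = 0.180 with an estimated correlation). Their median of -0.462 had a 95% bootstrap interval of -1.08 to 0.01 that reaches 0. The bootstrap, here and below, resampled the genes of a list and not the arrays. Its intervals thus do not measure the spread between samples. A response to the 16 days of PLX4032 also stays open, as no other drug or time was analysed here to test it.

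FOS (1.98 ± 0.07), JUN (2.73 ± 0.10) and EGR1 (0.83 ± 0.06) rose while the MAPK feedback genes SPRY4 and DUSP6 fell. Handling at harvest may raise immediate early genes within minutes. The 17 measured other immediate early and heat shock genes had a median of 0.0279 (95% bootstrap interval over genes -0.61 to 0.50). As a list they had a camera adjusted p of 0.567, with 5 higher, 8 lower and 4 not called. The median thus joins changes in both directions. The 5 that rose were the immediate early genes JUNB (0.84), IER2 (0.67), FOSB (0.57), JUND (0.55) and KLF6 (0.50). Those that fell were EGR3 (-2.73), HSPH1, BAG3, DNAJB1, HSPA8, NR4A2, NR4A1 and DUSP1 (-0.28). Handling therefore cannot be told apart from a response to the drug. The 5 measured heat shock genes had a median of -0.627 (-1.40 to 0.03), with HSPH1 (-1.40) and HSPA8 (-0.61) lower and HSPB1 (0.03) not called. They did not lie higher as a set. This subset was chosen after the values had been seen, and HSPA1A and HSPA1B were not measured, so it does not decide on heat stress alone.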
